A study of Mus musculus with 18 samples.

How the data were processed

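Gene expression was measured by mRNA sequencing in AT-3 and E0771, mouse mammary carcinoma lines carrying a doxycycline-inducible retroviral vector (pRetroX) that was empty or held wild-type or Y238A MRTFA. All cultures had doxycycline at 2 µg/ml for 48 h, and each of the 6 groups had 3 libraries, 18 in all. Per the labels, RNA was purified with RNeasy columns, libraries were made with the NuGen Universal Plus mRNA kit, reads were aligned to GRCm38 with STAR and counted with featureCounts, without versions. The deposited file holds raw counts per gene in 32286 entries, 32158 of them with a gene symbol by Ensembl ID, 127 with an ID alone, and 1 named MRTFA, taken here as the construct. The labels give no annotation release or strandedness, and do not say how the MRTFA entry was made or from which species the cDNA came. Of the symbols, 26 belonged to more than 1 entry, and genes were analysed by ID.

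Library totals lay between 81265466 and 115260128 counts, and CPM are counts over these totals after TMM scaling. Between 61.9% and 64.6% of nonzero counts were even, and among counts of 1 or 2 between 82.1% and 85.5% were 2, so both mates of a read pair appear to have been counted and counting intervals are too narrow. With 3 libraries per group the 18 libraries left 12 residual degrees of freedom. The precision was tested on simulated data with known changes: the test recovered 31.3% to 56.7% of genes changed 1.5-fold, 55.2% to 74.6% at 2-fold and 65.2% to 84.8% at 4-fold, with 3 to 8 false calls and 0 in the wrong direction, and it called the 1 raised list, 2 lists sharing its genes and 0 others of 28.

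Counts were analysed in R 4.3.3 with edgeR 4.0.16, keeping 17841 genes by filterByExpr on the groups (minimum count 10, minimum total 15), with TMM scaling, robust dispersions and the robust quasi-likelihood F test in a fit of all 18 libraries with 6 group means. Per line the contrasts were wild type against empty vector, Y238A against empty vector and wild type against Y238A, and each was also compared between lines as the E0771 effect minus the AT-3 effect. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Replicate numbers were left out of the model. Calls shared between lines were counted against the product of the call rates with Fisher's exact test, and for the constructs within a line the share of genes with the same sign was set beside 20 simulations of unchanged groups with the same 3 control libraries.

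Gene lists, 28 in all, were drawn from the cell type, the factor and the ions in the series title. Each was tested with camera in limma 3.58.1 (preset correlation 0.01, at least 5 genes tested), adjusted over lists within a comparison. The directions of members were counted over all genes, and the count adjusted over the list alone is given where it differs. Named genes followed a fixed order: Mrtfa, Srf and Mrtfb, then from the top of the 10 highest and 10 lowest log2 fold changes past the threshold with a mean of at least 1 CPM, non-overlapping groups and a symbol that is not a model name, then up to 4 list members by smallest p, 10 genes per direction for changes shared by lines and 5 for line differences. For room, fewer genes are named than the order allows, and some members further down it are named beside others. Some genes of that order and 1 of the 28 lists are not reported here. A gene with 0 counts in a group is given a bound, with the floor at 3 counts over the group, and one with 1 to 3 counts a 95% counting interval.

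Transcripts of other groups were measured in 240 genes with a mean over 20 CPM and a lowest value over 10 CPM in AT-3 and a median under 0.3 CPM in E0771, and in 32 genes over 10 CPM in AT-3 with wild-type MRTFA and under 0.02 CPM with empty vector, as the median percent of the source level. No library was left out of the main test. Alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals, no filter, a stricter filter (at least 1 CPM in 3 libraries and a mean of 50 counts), each line fitted alone, a replicate block, an added limit of 1 on the absolute log2 fold change, each library left out in turn, and for lists an estimated correlation and fry. After the data were seen, analyses without the 4 libraries of highest carry-over (AT-3 Y238A replicate 1, E0771 empty vector replicate 2, E0771 wild-type replicate 2 and E0771 Y238A replicate 1) and with only genes of at least 1 CPM were added.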

Results

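The question was how 48 h of induced MRTFA, an actin-regulated coactivator of the transcription factor SRF, changed gene expression in AT-3 and E0771, a pair of mouse mammary carcinoma lines. The constructs were an empty retroviral vector, wild-type MRTFA and Y238A MRTFA, which the labels describe as deficient in SRF binding. Each construct and line had 3 libraries, 18 in all, under doxycycline. The labels name no separate cultures, so the 3 may be technical replicates, and effects of construct and culture cannot be told apart. Values are log2 fold changes ± SE or CPM ± SD, n = 3 per group, and a gene or list counts as changed past an adjusted p of 0.05. Beside each list stand its members that passed, the rest not passing, the median log2 fold change and the adjusted p of the list test. Fold values given as "at least" or with an interval cover counting error alone, and they are too narrow because read mates appear to have been counted separately. Gene lists, comparisons and the order of named genes were fixed before the data were examined. For every count of genes, whether more were higher or lower turned in at least 1 alternative, and only some of these are given beside it.

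Some libraries held transcripts of another group. Across 240 genes expressed in AT-3 and near absent from E0771, E0771 empty vector replicate 2 held a median 1.35% of the AT-3 empty vector level, E0771 wild-type replicate 2 held 0.508% of the AT-3 wild-type level and E0771 Y238A replicate 1 held 0.269% of the AT-3 Y238A level, against at most 0.0616% in the other E0771 libraries. Across 32 genes seen in AT-3 with wild-type MRTFA alone, AT-3 Y238A replicates 1, 2 and 3 held 1.27%, 0.264% and 0.110% of the wild-type level. Such transcripts compress or inflate the fold values of genes that a group hardly expresses, and the value without that library is given where that of a named gene moved. Apart from this, AT-3 wild-type replicate 1 and E0771 Y238A replicate 2 stood apart from the other 2 libraries of their groups (chi-square of counts per degree of freedom 40.1 and 51.8 against 7.12 between those 2, and 57.3 and 68.4 against 12), and the former had the most genes with at least 10 counts (17399).

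**Figure D1:**
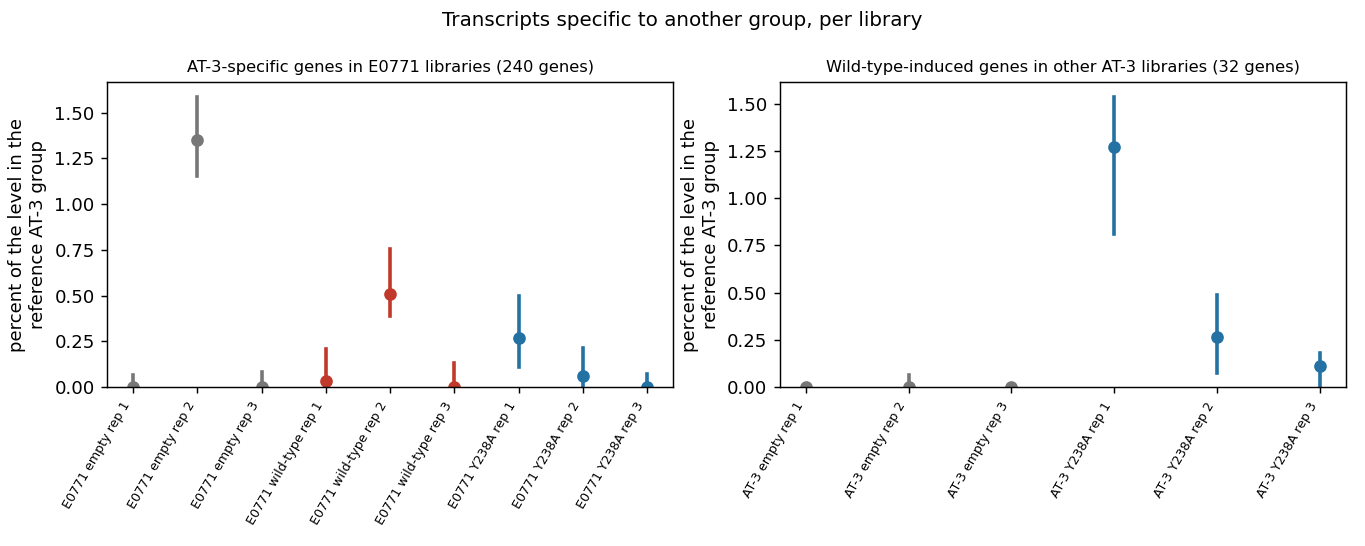
Share of another group's specific transcripts in each library, as a percent of the level in the reference AT-3 group (median over genes). The genes of the wild-type panel were chosen for absence with AT-3 empty vector. E0771 empty vector replicate 2 (1.35%) and AT-3 Y238A replicate 1 (1.27%) stand highest.

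The MRTFA construct, counted as a separate entry in the deposited counts, was present where the labels place it and was more abundant as wild type than as Y238A. In AT-3 it reached 5434 ± 1445 CPM as wild type and 2105 ± 195 CPM as Y238A, against 0.0160 ± 0.0138 CPM with empty vector. In E0771 the levels were 761 ± 91.1, 319.7 ± 37.4 and 0.0736 ± 0.0639 CPM. Wild type exceeded Y238A by 1.37 ± 0.20 in AT-3 (adjusted p = 5.01e-05) and by 1.25 ± 0.20 in E0771 (adjusted p = 4.49e-04), so every comparison of the constructs also compares different amounts of transcript. The mouse gene itself, Mrtfa (ENSMUSG00000042292, chromosome 15, 81012281 to 81190757, GRCm38), fell with wild-type MRTFA in AT-3, by 0.51 ± 0.04. Its other log2 fold changes against empty vector were 0.10 with Y238A in AT-3 (adjusted p = 0.0651), -0.04 with wild type in E0771 (adjusted p = 0.517) and 0.03 with Y238A in E0771 (adjusted p = 0.744). Srf (ENSMUSG00000015605, chromosome 17, 46548329 to 46556175) rose with wild-type MRTFA by 1.65 ± 0.07 in AT-3 and 1.21 ± 0.07 in E0771. With Y238A it fell by 1.0 ± 0.07 in AT-3 and by 0.26 ± 0.07 in E0771 (adjusted p = 0.0258, lost at 0.0793 without empty vector replicate 1, 0.106 without empty vector replicate 2, 0.0859 without Y238A replicate 2 and 0.0559 with library totals). Mrtfb, the paralogue, fell with wild-type MRTFA by 0.97 ± 0.05 in AT-3 and 0.24 ± 0.05 in E0771, and with Y238A by 0.25 ± 0.05 in AT-3 (-0.07 in E0771, adjusted p = 0.444).

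**Figure D2:**
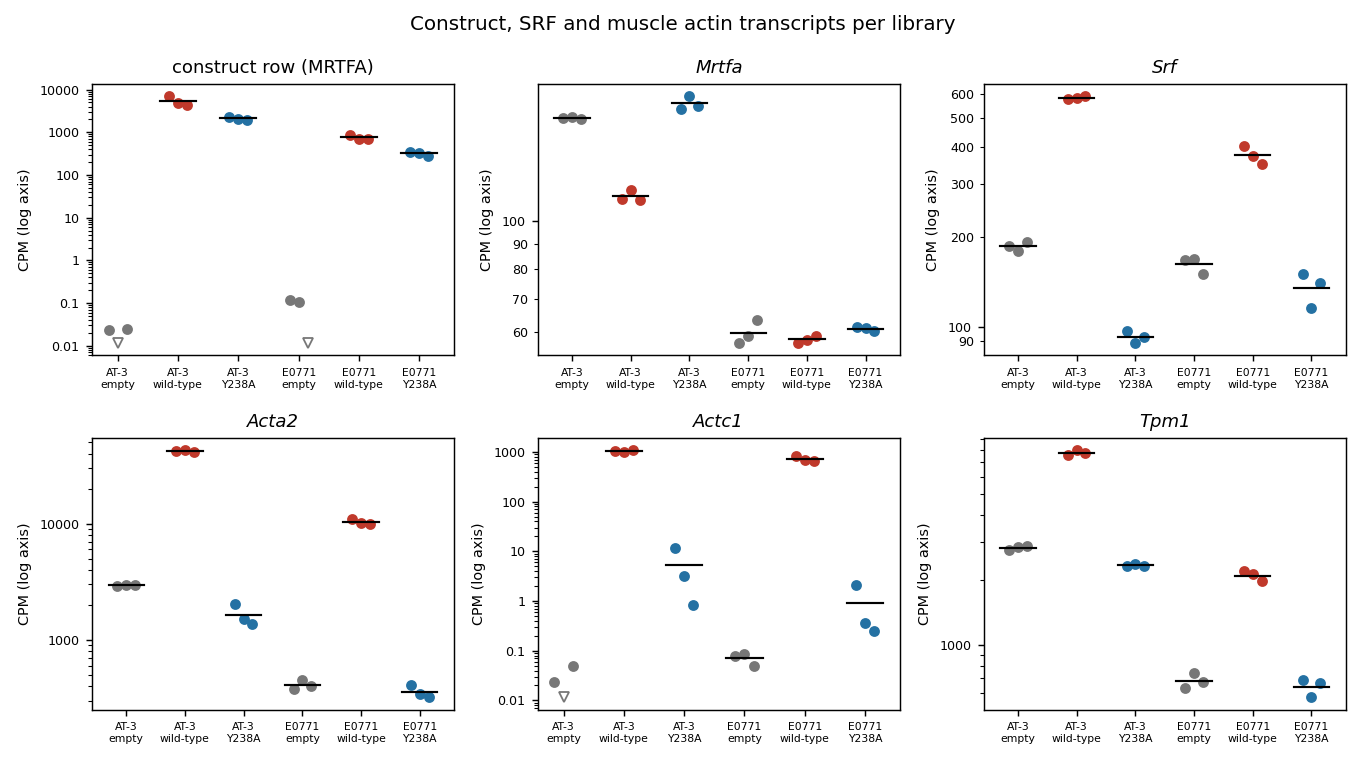
CPM of the MRTFA construct, Mrtfa, Srf, Acta2, Actc1 and Tpm1 in each library (log axis, open triangles at 0 counts, lines are group means). Acta2 stood at 10348 CPM with wild-type MRTFA in E0771 and 410.1 CPM with empty vector.

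Wild-type MRTFA against empty vector in AT-3 asked what differed with the SRF-competent construct, and genes silent with empty vector rose. Uts2b, a urotensin peptide precursor (ENSMUSG00000056423, chromosome 16, 27353322 to 27370239), was at least 10297-fold higher, from 0 counts over the 3 empty vector libraries. Heph, a membrane ferroxidase (at least 8336-fold higher), Havcr1, a surface receptor (at least 8286-fold higher), and Slc24a1, a potassium-dependent sodium-calcium exchanger (at least 4722-fold higher), also started from 0 counts. Cardiac actin Actc1 (ENSMUSG00000068614, chromosome 2, 114047282 to 114053548) rose by 15.41 ± 1.22, or 16.39 without empty vector replicate 3, and the lens crystallin Cryaa was 14952-fold higher by counts, interval 2683 to 590599.8, log2 value moving from 13.44 to 15.40 without empty vector replicate 2. The largest decreases were in Igfbp5, an IGF-binding protein (-5.47 ± 0.23), Ogn, a small proteoglycan (-5.10 ± 0.33), Inhbb, an activin subunit (-4.74 ± 0.32), and Ccn5, a matricellular protein (-4.53 ± 0.18), followed by Cdh15 (-4.22 ± 0.41, or -4.84 without wild-type replicate 2), Chdh (-4.18 ± 0.56, or -4.93 without wild-type replicate 2) and Cyp1b1 (-4.16 ± 0.49).

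Contractile and cytoskeletal lists rose in AT-3 with wild-type MRTFA. 34 of 40 MRTF-SRF cytoskeletal targets rose and 3 fell (median 1.38, adjusted p = 8.69e-15, lost at adjusted p = 0.158 with an estimated correlation). Csrp1 (2.61 ± 0.06) and Pdlim5 (1.90 ± 0.05) rose. 22 of 22 smooth muscle contractile genes rose and 0 fell (median 3.66, adjusted p = 5.50e-12, lost at adjusted p = 0.158 with an estimated correlation). Tpm2 (3.07 ± 0.06) rose. 24 of 31 sarcomere and striated muscle genes rose and 2 fell (median 5.25 or 4.75 with bounds, adjusted p = 7.80e-04, lost at adjusted p = 0.169 with an estimated correlation). Actn2 (9.75 ± 0.39, or 10.62 without empty vector replicate 2) and Myh6 (11.16 ± 0.53) rose. 20 of 25 SRF-TCF immediate early genes rose and 1 fell (median 1.94, adjusted p = 2.68e-08, lost at adjusted p = 0.158 with an estimated correlation). Ier2 (1.54 ± 0.05) and Zfp36 (2.57 ± 0.10) rose. 23 of 45 integrin and focal adhesion genes rose and 12 fell (median 0.39, adjusted p = 0.00200, lost at adjusted p = 0.364 with an estimated correlation). The fibronectin receptor subunit Itga5 rose (3.01 ± 0.05). The following lists did not pass. YAP-TEAD targets had 9 higher and 9 lower of 22 (10 and 9 adjusted over the list alone, median 0.02, mean 0.30, test direction down, adjusted p = 0.519). Fibrillar collagens and matrix proteins had 14 higher and 17 lower of 48 (median -0.20, mean 0.14, test direction down, adjusted p = 0.654). Epithelial genes had 8 higher and 8 lower of 31 (8 and 7 adjusted over the list alone, median 0.13, adjusted p = 0.519). Mesenchymal and EMT genes had 11 higher and 15 lower of 31 (median -0.40, adjusted p = 0.144). Within them Col18a1 (3.20 ± 0.07) and keratin Krt19 (3.11 ± 0.14) rose, and Myof (-1.54 ± 0.05) and vimentin Vim (-1.78 ± 0.07) fell.

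Of the calcium and potassium genes that the series title names, no list passed in AT-3, where 68.6% of all genes tested changed one by one. Calcium pumps, channels and stores had 49 higher and 18 lower of 83 (median 1.02, adjusted p = 0.0851, passing at 0.0280 without the 4 libraries of highest carry-over). Calcium-binding and calmodulin genes had 18 higher and 31 lower of 56 (median -0.26, adjusted p = 0.125). Potassium channels had 31 higher and 6 lower of 52 (median 1.89, adjusted p = 0.0575, passing at 0.0279 with library totals, 0.0247 without the 4 libraries of highest carry-over and 0.0481 without wild-type replicate 3). Sodium-potassium pump, cotransport and volume channels had 18 higher and 12 lower of 37 (median 0.41, adjusted p = 0.264). The endoplasmic reticulum calcium release channel Itpr3 (-1.71 ± 0.05) and the cation channel Pkd2 (-1.17 ± 0.05) fell, while the store-operated channel Orai1 (1.5 ± 0.07) and its regulator Saraf (1.15 ± 0.06) rose. Among potassium channel genes Kcnh2 (4.44 ± 0.17), Kcnip3 (4.69 ± 0.30) and Kcnv2 (10.01 ± 0.55, or 14.23 without empty vector replicate 3) rose and the calcium-activated channel Kcnn4 fell (-1.78 ± 0.07). The sodium-pump subunit Atp1b3 (1.47 ± 0.04) rose. Phospholipase Plcd3 (2.92 ± 0.07) rose and annexin Anxa4 (-1.85 ± 0.06) fell.

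Proliferation, ribosome and interferon lists fell in AT-3. 2 of 42 S-phase genes rose and 34 fell (median -0.69, adjusted p = 1.33e-08, lost at adjusted p = 0.434 with an estimated correlation). Uhrf1 (-1.63 ± 0.07) and Pola1 (-1.09 ± 0.06) fell. 6 of 51 G2/M genes rose and 43 fell (6 and 44 adjusted over the list alone, median -0.60, adjusted p = 7.41e-08, lost at adjusted p = 0.434 with an estimated correlation). Kif23 (-1.5 ± 0.07) fell. 2 of 77 cytosolic ribosomal proteins rose and 74 fell (median -0.66, adjusted p = 9.05e-16, lost at adjusted p = 0.434 with an estimated correlation). Rpl23a (-1.04 ± 0.05) fell. 4 of 37 interferon-stimulated genes rose and 29 fell (median -1.13, adjusted p = 1.26e-04, lost at adjusted p = 0.434 with an estimated correlation). Irgm1 (-1.73 ± 0.07) and Trim25 (-1.13 ± 0.06) fell. 3 of 24 cholesterol synthesis genes rose and 19 fell (median -0.89, adjusted p = 0.00436, lost at adjusted p = 0.558 with an estimated correlation). The MHC class I and p53 lists rose. 13 of 25 genes of MHC class I, antigen processing and NK ligands rose and 5 fell (median 0.51, adjusted p = 0.00436, lost at adjusted p = 0.169 with an estimated correlation). B2m (1.37 ± 0.03) and Nlrc5 (2.49 ± 0.08) rose. 12 of 26 p53 targets rose and 9 fell (median 0.35, adjusted p = 0.0416, lost at 0.0597 with library totals, 0.0668 without empty vector replicate 1 and 0.0555 without wild-type replicate 3, lost at adjusted p = 0.364 with an estimated correlation). Pmaip1 (5.29 ± 0.12) rose.

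The remaining lists did not pass in AT-3. NF-kB and inflammatory cytokine genes had 7 higher and 11 lower of 26 (median -0.40, mean 0.08, test direction down, adjusted p = 0.125). Unfolded protein and integrated stress response genes had 15 higher and 10 lower of 32 (median 0.07, adjusted p = 0.105). Glycolysis and hypoxia genes had 18 higher and 8 lower of 34 (median 0.32, adjusted p = 0.0514, passing at 0.0453 with DESeq2 size factors, 0.0328 without wild-type replicate 1, 0.0408 without empty vector replicate 2, 0.0447 without wild-type replicate 2 and 0.0481 without wild-type replicate 3). Mitochondrially encoded genes had 10 higher and 0 lower of 13 (11 and 0 adjusted over the list alone, median 0.65, adjusted p = 0.114). Edem1 (2.64 ± 0.05), Pfkfb3 (1.46 ± 0.06) and mt-Nd2 (0.65 ± 0.07) rose, and Csf1 (-1.72 ± 0.08) fell. Nor did markers of other cell types pass. Fibroblast markers had 1 higher and 2 lower of 7 (median 0.21, mean 0.45, test direction down, adjusted p = 0.825). Leukocyte and macrophage markers had 3 higher and 2 lower of 7 (median 0.60, adjusted p = 0.743). Endothelial and adipocyte markers had 4 higher and 0 lower of 7 (3 and 0 adjusted over the list alone, median 2.38 or 2.33 with bounds, adjusted p = 0.726). Cd68 (2.61 ± 0.15) and Tek (3.92 ± 1.16) rose, and Pdgfra (-2.47 ± 0.19) fell. In the edgeR test 6497 higher and 5743 lower genes passed among 17841, 4152 and 1698 of them by at least 2-fold, and in 74.5% of genes the groups were non-overlapping, against 10% by chance. With library totals instead of TMM the median of all genes moved by -0.139 and the majority turned, to 5668 higher and 6910 lower.

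Wild-type MRTFA against empty vector in E0771 asked the same of the second line, and smooth muscle and cardiac actin were among the genes that rose. Smooth muscle actin Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590) rose from 410.1 ± 37.1 to 10348 ± 585 CPM (4.66 ± 0.14), and Actc1 rose by 13.30 ± 1.09. From 0 counts, cyclin A1 Ccna1 was at least 523-fold higher, the GABA receptor subunit Gabra3 at least 510.1-fold higher and Plac8 at least 328-fold higher. The mucin Muc3a was 2024-fold higher by counts, interval 560.0 to 16720.3, log2 value moving from 10.72 to 13.31 without empty vector replicate 1. The actin nucleator Cobl (10.21 ± 1.05, or 13.69 without empty vector replicate 2) and the subunit Kcnmb1 of a calcium-activated potassium channel (9.43 ± 0.43, or 11.08 without empty vector replicate 2) also rose. Decreases were smaller: Ccn5 (-1.83 ± 0.22), Fam19a5 (-1.49 ± 0.26), Kctd14 (-1.37 ± 0.29), Gja4 (-1.35 ± 0.36), Fam180a (-1.33 ± 0.25) and Sulf2 (-1.31 ± 0.13), the call for Gja4 being lost at adjusted p = 0.0620 without the 4 libraries of highest carry-over.

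In E0771 the SRF, muscle, integrin and MHC class I lists rose, and their calls held with an estimated correlation. 38 of 40 MRTF-SRF cytoskeletal targets rose and 1 fell (median 1.58, adjusted p = 1.30e-135, held at adjusted p = 4.15e-05 with an estimated correlation). Pdlim5 (1.99 ± 0.05) and Csrp1 (2.68 ± 0.06) rose. 19 of 22 smooth muscle contractile genes rose and 0 fell (median 1.80, adjusted p = 6.38e-42, held at adjusted p = 0.00145 with an estimated correlation). Tpm2 (2.33 ± 0.06) and Tpm1 (1.62 ± 0.06) rose. 17 of 31 sarcomere and striated muscle genes rose and 0 fell (median 1.13, adjusted p = 1.02e-12, held at adjusted p = 0.00324 with an estimated correlation). Actn2 (5.04 ± 0.29) and Myom1 (3.27 ± 0.24) rose. 20 of 45 integrin and focal adhesion genes rose and 4 fell (21 and 6 adjusted over the list alone, median 0.15, adjusted p = 3.12e-16, held at adjusted p = 0.00414 with an estimated correlation). Itga5 (2.39 ± 0.05) and Vcl (1.55 ± 0.04) rose. 14 of 25 genes of MHC class I, antigen processing and NK ligands rose and 1 fell (median 0.28, adjusted p = 2.07e-07, held at adjusted p = 0.00494 with an estimated correlation). B2m (0.61 ± 0.03) and Nlrc5 (0.96 ± 0.08) rose. Other lists passed in the preset test alone, the smallest value among them being adjusted p = 0.105 with an estimated correlation. These lists rose. SRF-TCF immediate early genes had 14 higher and 1 lower of 25 (14 and 2 adjusted over the list alone, median 0.66, adjusted p = 1.88e-07). YAP-TEAD targets had 10 higher and 2 lower of 22 (median 0.21, adjusted p = 8.37e-05). Potassium channels had 13 higher and 2 lower of 52 (median 0.04 or 0.02 with bounds, adjusted p = 6.38e-04). Mesenchymal and EMT genes had 11 higher and 7 lower of 31 (median -0.09, mean 0.36, test direction up, adjusted p = 7.22e-04). The p53 targets had 7 higher and 1 lower of 26 (median -0.01, mean 0.25, test direction up, adjusted p = 0.0135, lost at 0.0780 with a replicate block). Interferon-stimulated genes had 11 higher and 0 lower of 37 (14 and 0 adjusted over the list alone, median 0.26, adjusted p = 0.0231, lost at 0.0535 without empty vector replicate 3 and 0.0812 without wild-type replicate 3). Zfp36 (1.60 ± 0.10) and Crim1 (1.08 ± 0.06) rose. Kcnip3 (6.45 ± 0.38), Kcnh2 (1.09 ± 0.10), Pmaip1 (1.63 ± 0.10) and Gbp2 (1.83 ± 0.13) rose. The EMT median became 0.32 without empty vector replicate 2, and the p53 median 0.02, 0.03, 0.04 or 0.02 without empty vector replicate 1, wild-type replicate 1, empty vector replicate 2 or wild-type replicate 3. S-phase, G2/M and ribosomal lists fell. S-phase genes had 0 higher and 28 lower of 42 (1 and 33 adjusted over the list alone, median -0.26, adjusted p = 1.12e-07). G2/M genes had 2 higher and 28 lower of 51 (4 and 30 adjusted over the list alone, median -0.19, adjusted p = 2.10e-04). Cytosolic ribosomal proteins had 0 higher and 27 lower of 77 (0 and 35 adjusted over the list alone, median -0.13, adjusted p = 2.10e-04). Pcna (-0.35 ± 0.04) and Nusap1 (-0.55 ± 0.08) fell.

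The calcium and sodium pump lists did not pass in E0771. Calcium pumps, channels and stores had 17 higher and 12 lower of 83 (20 and 12 adjusted over the list alone, median 0.06 or 0.04 with bounds, adjusted p = 0.398). Calcium-binding and calmodulin genes had 13 higher and 14 lower of 56 (13 and 16 adjusted over the list alone, median -0.10, mean 0.06, test direction up, adjusted p = 0.498). Sodium-potassium pump, cotransport and volume channels had 8 higher and 7 lower of 37 (8 and 8 adjusted over the list alone, median -0.09, mean 0.13, test direction up, adjusted p = 0.942). The junctional membrane protein Jph2 (3.18 ± 0.31) and the cation channel Trpv2 (2.87 ± 0.21) rose. Itpr3 (-0.47 ± 0.05) fell. A further set of lists did not pass. Fibrillar collagens and matrix proteins had 12 higher and 12 lower of 48 (median -0.16, mean 0.04, test direction up, adjusted p = 0.452, passing at 0.00102 without the 4 libraries of highest carry-over and 0.00691 without empty vector replicate 2). Epithelial genes had 5 higher and 1 lower of 31 (median 0.16, adjusted p = 0.385). NF-kB and inflammatory cytokine genes had 8 higher and 2 lower of 26 (8 and 3 adjusted over the list alone, median 0.03, adjusted p = 0.240, passing at 0.0317 without the 4 libraries of highest carry-over). Cholesterol synthesis genes had 0 higher and 6 lower of 24 (median -0.14, adjusted p = 0.0839, passing at 0.00555 with a replicate block and 0.0250 without empty vector replicate 1). Unfolded protein and integrated stress response genes had 2 higher and 3 lower of 32 (median -0.01, mean 0.03, test direction up, adjusted p = 0.942). Glycolysis and hypoxia genes had 9 higher and 2 lower of 34 (median 0.01, adjusted p = 0.240). Mitochondrially encoded genes had 0 higher and 0 lower of 13 (median -0.03, adjusted p = 0.886). Lamb1 (1.86 ± 0.08), Krt7 (2.06 ± 0.24), Relb (0.93 ± 0.08) and Slc2a1 (0.67 ± 0.04) rose. Markers of other cells did not pass. Fibroblast markers had 2 higher and 3 lower of 7 (median -0.88, mean 0.29, test direction down, adjusted p = 0.452). Leukocyte and macrophage markers had 0 higher and 0 lower of 7 (median -0.14, adjusted p = 0.673). Endothelial and adipocyte markers had 0 higher and 0 lower of 7 (median -0.06, adjusted p = 0.730). Without empty vector replicate 2, which held 1.35% of AT-3 empty vector transcripts, the medians of collagens and fibroblast markers became 0.35 and 0.40. The edgeR test passed 2000 higher and 2364 lower genes, 983 and 102 of them by at least 2-fold, with groups non-overlapping in 41.5% of genes against 10% by chance. Without the 4 libraries of highest carry-over 1667 were higher and 1118 lower, and the majority also turned with the stricter filter (2154 and 1385) and with this line fitted alone (1952 and 1417).

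**Figure D3:**
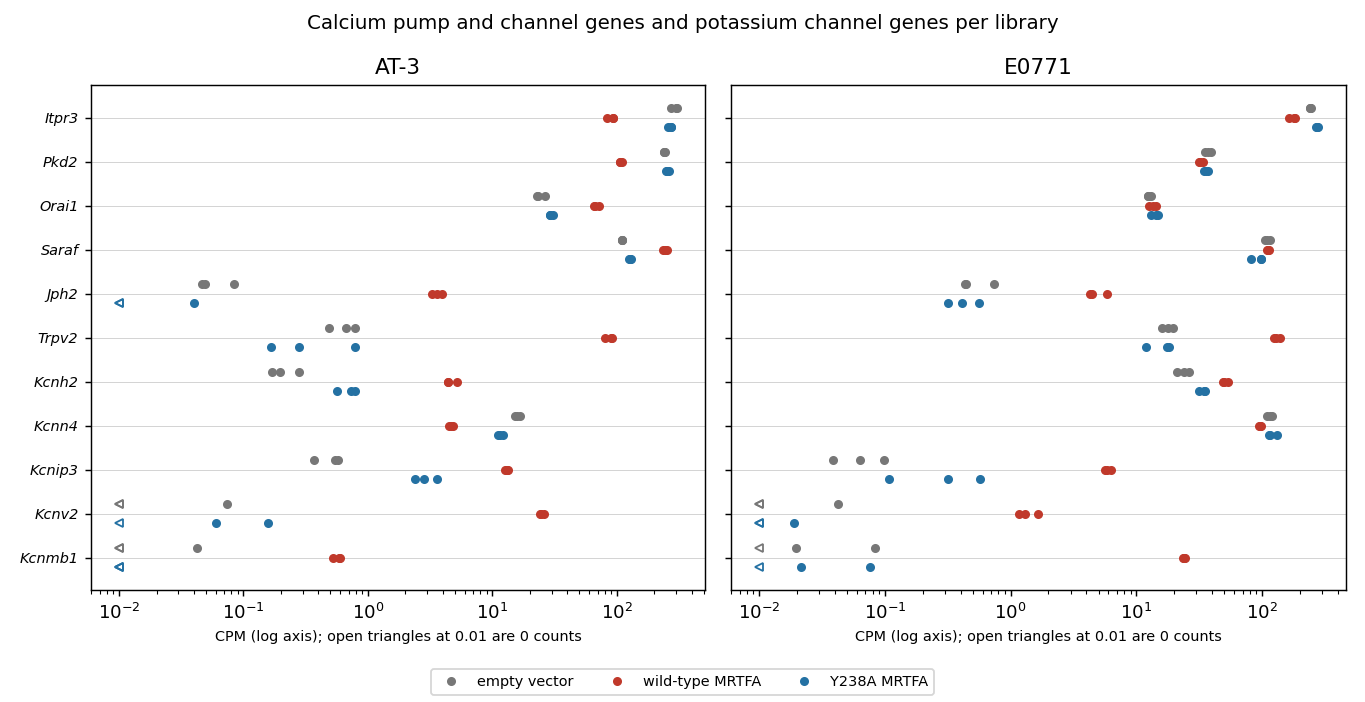
CPM per library of calcium and potassium genes changed at least 2-fold by wild-type MRTFA in either line (log axis, open triangles at 0 counts). Itpr3 was lower with wild-type MRTFA than with empty vector in AT-3 (-1.71) and E0771 (-0.47).

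Changes shared by the lines were counted to ask which wild-type effects were common to both, and the cardiac and skeletal actins were among them. Actc1, Muc3a, Cobl, Ccna1, Gabra3 and the skeletal actin Acta1 (9.16 ± 1.01 in AT-3 and 8.49 ± 1.01 in E0771) rose in both lines. Ccn5, Fam180a (-3.44 ± 0.28), Sulf2 (-2.45 ± 0.13) and Pdgfra (-2.47 ± 0.19) fell in both, the values being those of AT-3. In all, 1673 genes rose in both lines and 1737 fell in both, against 728 and 761 expected if the lines were unrelated, with odds ratios of 11.7 and 7.93 in Fisher's exact test across genes, which treats genes as independent. A further 409 genes passed with opposite signs. The shared total of 3410 was 2246 without the 4 libraries of highest carry-over, and more were higher than lower there (1397 and 849), with the stricter filter (1693 and 1084) and with each line fitted alone (1577 and 1068).

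**Figure D4:**
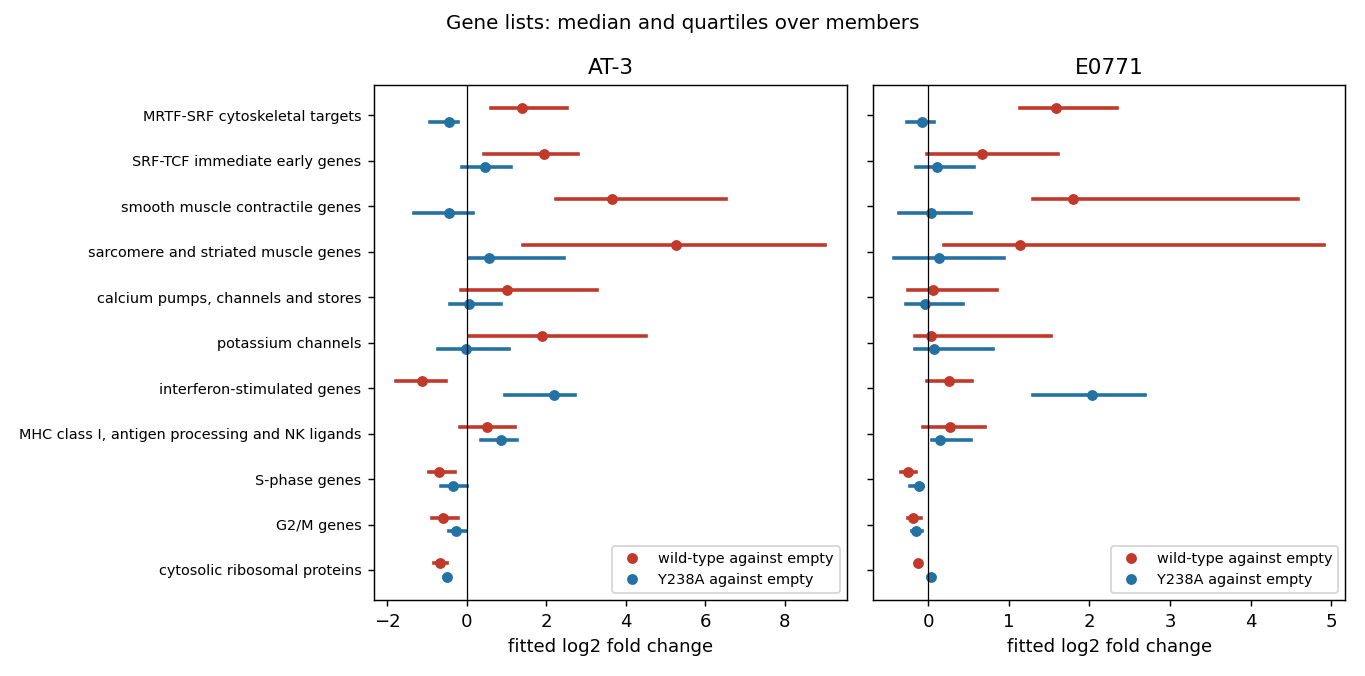
Median log2 fold change of selected gene lists for wild-type and Y238A MRTFA, each against empty vector, in both lines, with quartiles over genes. MRTF-SRF targets had a median of 1.38 in AT-3 and 1.58 in E0771 for wild-type MRTFA against empty vector, and interferon-stimulated genes 2.19 and 2.04 for Y238A.

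Y238A MRTFA against empty vector in AT-3 asked what differed with the construct labelled as deficient in SRF binding, and interferon genes rose while SRF targets fell. The phosphate cotransporter Slc34a2 was at least 191-fold higher, from 0 counts. Actc1 rose by 7.77 ± 1.60, or 6.39 without Y238A replicate 1, the library that held 1.27% of wild-type transcripts. Y238A replicates 2 and 3 held 0.264% and 0.110% of wild-type transcripts, so this rise cannot be told apart from carry-over. Hoxb13, a homeobox factor (7.62 ± 0.38, or 11.27 without empty vector replicate 2), the interferon-induced Rsad2 (6.12 ± 0.28), the Wnt antagonist Sfrp1 (6.11 ± 0.36), Rnf165 (6.01 ± 0.45) and the non-muscle myosin Myh14 (5.72 ± 0.40) rose. The cadherin Cdh15 (-4.56 ± 0.42), the Wnt antagonist Dkk2 (-3.56 ± 0.53) and keratin Krt7 (-3.47 ± 0.31) fell. So did the Hedgehog effector Gli1 (-3.26 ± 0.26), Cap2 (-3.19 ± 0.43) and Scn3a (-3.11 ± 0.43).

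Interferon and MHC class I lists rose in AT-3 with Y238A, and SRF target and smooth muscle lists fell. 35 of 37 interferon-stimulated genes rose and 1 fell (median 2.19, adjusted p = 2.49e-28, lost at adjusted p = 0.0629 with an estimated correlation). Ifit1 (3.18 ± 0.15), Gbp3 (2.73 ± 0.15) and Gbp2 (1.96 ± 0.12) rose. The leukocyte markers Cd68, a lysosomal protein (4.39 ± 0.16), and Cd14 (1.41 ± 0.13) rose with them, as did Cd74, which is outside that list (0.170 to 3.38 CPM, and 22 CPM with wild type, where the interferon list fell), and the 7 tested leukocyte markers had a median of -0.14 (upper quartile 0.81). 17 of 25 genes of MHC class I, antigen processing and NK ligands rose and 2 fell (median 0.87, adjusted p = 2.09e-11, held at adjusted p = 0.00306 with an estimated correlation). Tapbp (1.73 ± 0.07) and H2-K1 (1.10 ± 0.04) rose. 4 of 40 MRTF-SRF cytoskeletal targets rose and 30 fell (5 and 30 adjusted over the list alone, median -0.44, adjusted p = 4.06e-06, lost at adjusted p = 0.597 with an estimated correlation). Pdlim5 (-1.0 ± 0.05) and Tagln2 (-0.90 ± 0.05) fell. 4 of 22 smooth muscle contractile genes rose and 13 fell (4 and 14 adjusted over the list alone, median -0.44, adjusted p = 0.00678, lost at adjusted p = 0.597 with an estimated correlation). Nexn (-2.17 ± 0.09) and Smtn (-0.63 ± 0.06) fell. Others passed in the preset test alone, the smallest value being adjusted p = 0.597 with an estimated correlation. Of these, immediate early, calcium-binding and mitochondrial lists rose. SRF-TCF immediate early genes had 12 higher and 6 lower of 25 (14 and 6 adjusted over the list alone, median 0.46, adjusted p = 0.00576). Calcium-binding and calmodulin genes had 21 higher and 11 lower of 56 (median 0.18, adjusted p = 0.0259). Mitochondrially encoded genes had 11 higher and 0 lower of 13 (median 0.58, adjusted p = 0.0408, lost at 0.0843 without empty vector replicate 1, 0.0518 without empty vector replicate 2 and 0.0535 without Y238A replicate 2). Ier3 (1.07 ± 0.06) and Camkk1 (2.92 ± 0.12) rose. YAP-TEAD, cell cycle and ribosomal lists fell. YAP-TEAD targets had 3 higher and 11 lower of 22 (median -0.40, adjusted p = 0.0408, lost at 0.0518 without empty vector replicate 2). S-phase genes had 4 higher and 28 lower of 42 (5 and 28 adjusted over the list alone, median -0.34, adjusted p = 3.49e-06). G2/M genes had 4 higher and 31 lower of 51 (median -0.26, adjusted p = 8.47e-05). Cytosolic ribosomal proteins had 0 higher and 76 lower of 77 (median -0.49, adjusted p = 5.43e-26). Asap1 (-0.85 ± 0.06), Nasp (-0.64 ± 0.05) and Rpl36 (-0.75 ± 0.05) fell.

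Ion channel lists did not pass with Y238A in AT-3. Calcium pumps, channels and stores had 24 higher and 16 lower of 83 (24 and 17 adjusted over the list alone, median 0.06 or 0.04 with bounds, adjusted p = 0.677). Potassium channels had 6 higher and 5 lower of 52 (6 and 3 adjusted over the list alone, median -0.02, mean 0.00, test direction down, adjusted p = 0.930). Sodium-potassium pump, cotransport and volume channels had 11 higher and 7 lower of 37 (median -0.04, mean -0.03, test direction up, adjusted p = 0.310). The L-type channel Cacna1c fell (-1.37 ± 0.11), the mechanosensitive channel Piezo1 rose (0.88 ± 0.07), and Kcnip3 (2.55 ± 0.29) and Kcnh2 (1.70 ± 0.21) rose. The edgeR test passed 3825 higher and 3963 lower genes, 1272 and 572 by at least 2-fold, with groups non-overlapping in 56.9% of genes against 10% by chance. The majority turned with library totals (4030 higher and 3768 lower), with the line fitted alone (4336 and 4313) and without empty vector replicate 3 (3510 and 3503).

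Y238A MRTFA against empty vector in E0771 raised interferon genes, in answer to the same question. The interferon-induced genes Ifit3b (4.83 ± 0.39, or 5.42 without empty vector replicate 2), Iigp1 (4.17 ± 0.46), Ifit3 (3.68 ± 0.25) and Ifi206 (3.43 ± 0.39) rose, with apolipoprotein D Apod (4.22 ± 0.29). Decreases were in the anticoagulant protein S gene Pros1 (-1.64 ± 0.14), Anxa8 (-1.51 ± 0.27), Sema3a (-1.22 ± 0.21) and Ccn5 (-1.21 ± 0.20), and further down Vdr (-1.14 ± 0.13) and the HLH inhibitors Id3 (-1.04 ± 0.14) and Id2 (-1.02 ± 0.13). Col12a1 (-1.52 ± 0.44, or -0.69 without empty vector replicate 2) ranked second, its call lost at adjusted p = 0.0870 without that library, which held 1.35% of AT-3 empty vector transcripts, and at 0.0724, 0.116 and 0.0924 without Y238A replicates 1, 2 and 3.

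All measured interferon-stimulated genes passed in E0771 with Y238A. 37 of 37 interferon-stimulated genes rose and 0 fell (median 2.04, adjusted p = 5.03e-180, held at adjusted p = 2.87e-05 with an estimated correlation). Irgm1 (1.76 ± 0.07), Irf7 (3.04 ± 0.14) and Oas3 (3.14 ± 0.14) rose. The leukocyte marker Cd68 (1.86 ± 0.15) rose with them, as did Cd74, which is outside that list (0.692 to 3.39 CPM), and the 7 tested leukocyte markers had a median of -0.31 (upper quartile 0.20). 9 of 25 genes of MHC class I, antigen processing and NK ligands rose and 2 fell (10 and 2 adjusted over the list alone, median 0.14, adjusted p = 2.36e-05, held at adjusted p = 0.0393 with an estimated correlation). Tapbp (1.13 ± 0.07) and Erap1 (0.53 ± 0.07) rose. Others passed in the preset test alone, the smallest value being adjusted p = 0.679 with an estimated correlation. Collagen and immediate early lists rose, and cell cycle and cholesterol lists fell. Fibrillar collagens and matrix proteins had 11 higher and 2 lower of 48 (13 and 3 adjusted over the list alone, median 0.10, mean -0.14, test direction up, adjusted p = 6.86e-04). SRF-TCF immediate early genes had 6 higher and 0 lower of 25 (7 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.0151, lost at 0.0969 without Y238A replicate 2). S-phase genes had 0 higher and 13 lower of 42 (0 and 15 adjusted over the list alone, median -0.11, adjusted p = 1.75e-05). G2/M genes had 0 higher and 13 lower of 51 (0 and 17 adjusted over the list alone, median -0.15, adjusted p = 3.43e-06). Cholesterol synthesis genes had 1 higher and 3 lower of 24 (3 and 12 adjusted over the list alone, median -0.26, adjusted p = 0.0197, lost at 0.540 without Y238A replicate 2 and 0.0843 without empty vector replicate 3). Col5a3 (0.85 ± 0.05) and Dusp6 (1.30 ± 0.10) rose, and Rrm1 (-0.33 ± 0.06) and Ndc80 (-0.39 ± 0.06) fell. The SRF target and ion lists did not pass. MRTF-SRF cytoskeletal targets had 3 higher and 11 lower of 40 (3 and 15 adjusted over the list alone, median -0.08, adjusted p = 0.329). Calcium pumps, channels and stores had 6 higher and 8 lower of 83 (median -0.04 or -0.02 with bounds, mean 0.18, test direction down, adjusted p = 0.962). Calcium-binding and calmodulin genes had 4 higher and 7 lower of 56 (5 and 7 adjusted over the list alone, median -0.03, adjusted p = 0.527). Potassium channels had 2 higher and 1 lower of 52 (2 and 0 adjusted over the list alone, median 0.07 or 0.00 with bounds, adjusted p = 0.456). Tes (0.59 ± 0.04) rose, and Actg1 (-0.30 ± 0.05) fell. The edgeR test passed 965 higher and 1184 lower genes, 301 and 57 by at least 2-fold, with groups non-overlapping in 26.1% of genes against 10% by chance. Without empty vector replicate 2 the count was 717 higher and 507 lower, without the 4 libraries of highest carry-over 516 and 331, and the majority also turned with library totals (1176 and 817) and the stricter filter (1285 and 889).

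**Figure D5:**
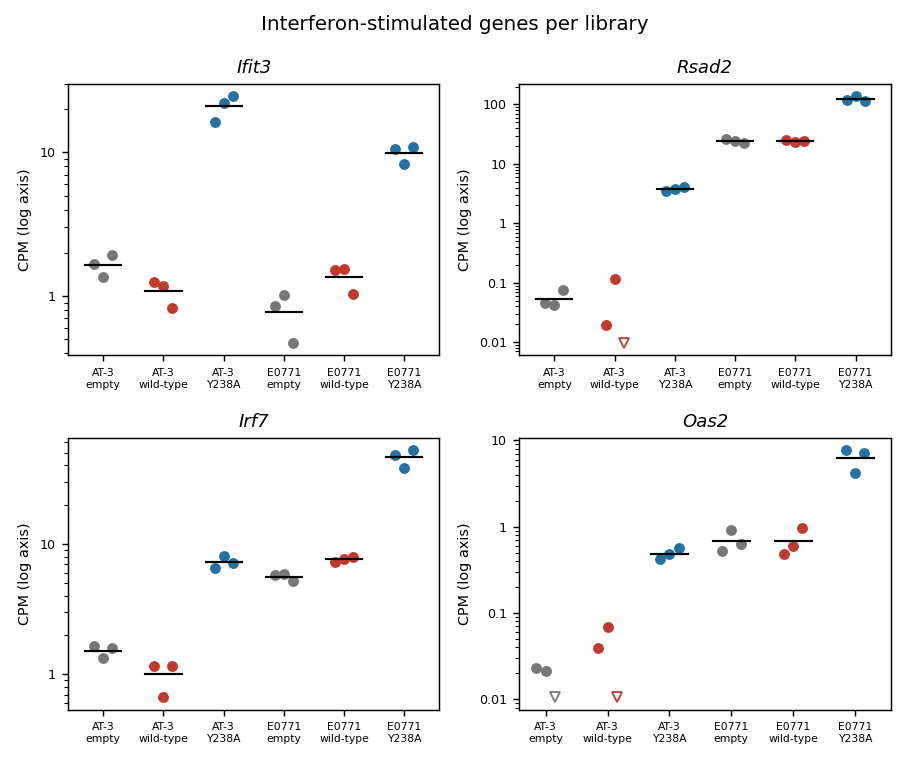
CPM per library of interferon-stimulated genes in both lines (log axis, points are libraries). Rsad2 was higher with Y238A MRTFA than with empty vector in AT-3 (6.12) and E0771 (2.31).

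To ask whether the constructs changed the same genes within a line, calls of each against the same empty vector libraries were crossed. In AT-3 1990 genes rose and 2420 fell with both constructs, against 1393 and 1276 if unrelated, and 1859 passed with opposite signs, Srf among them. In E0771 278 rose and 447 fell with both, against 108 and 157, and 277 passed with opposite signs. Vdr fell with both constructs in E0771 (-1.06 and -1.14), and Kcnip3, Kcnh2 and Cd68 rose with both in AT-3. Shared controls push these counts up, and 0 genes called for both in 20 simulations of unchanged groups against the same controls do not measure by how much in groups that change. The share of all genes with the same sign was 61.6% in AT-3 and 61.7% in E0771. The 68.5% and 68.6% of those simulations are likewise no reference for groups that change. The E0771 total of 725 moved to 383 without empty vector replicate 2 and 461 without empty vector replicate 3, and to 226 without the 4 libraries of highest carry-over. Higher genes then led at 224 to 159 without empty vector replicate 2 and 138 to 88 without the 4 libraries, as with the stricter filter (405 and 240) and with the line fitted alone (286 and 270).

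Wild-type against Y238A MRTFA in AT-3 asked what differed between the proteins, with more wild-type than Y238A transcript present (1.37). From 0 counts with Y238A, the signalling adaptor Lcp2 (ENSMUSG00000002699, chromosome 11, 34046920 to 34092295) was at least 436-fold higher, Mageb1 at least 403-fold higher and Acsm1 at least 333-fold higher, the call for Acsm1 being lost in DESeq2 (adjusted p = 0.0523). Y238A replicate 1 held 1.27% of wild-type transcripts, and muscle genes differed by more without it: Myh6 was higher by 8.12 ± 0.40, or 9.81 without Y238A replicate 1, Actc1 by 7.64 ± 0.74, or 9.02 without Y238A replicate 1 and Acta1 by 7.73 ± 0.95, or 9.34 without Y238A replicate 1. Lower with wild type were the surface proteins Ly6i, 302-fold lower by counts, interval 83.2 to 2497, log2 value moving from -7.99 to -10.71 without wild-type replicate 3, and Ly6c1 (-7.78 ± 0.14) and Ly6a (-7.56 ± 0.09), the interferon-induced Uba7 (-7.37 ± 0.41, or -9.57 without wild-type replicate 1) and the acute-phase gene Orm1 (-7.30 ± 0.57, or -10.89 without wild-type replicate 2).

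The interferon and SRF lists parted the proteins in AT-3. 0 of 37 interferon-stimulated genes were higher and 36 were lower (median -3.02, adjusted p = 1.04e-22, lost at adjusted p = 0.0980 with an estimated correlation). Ifit1 (-4.71 ± 0.17) and Irgm1 (-1.94 ± 0.07) were lower. The leukocyte marker Cd68 was lower with them (-1.78 ± 0.14). 36 of 40 MRTF-SRF cytoskeletal targets were higher and 3 were lower (median 1.81, adjusted p = 1.55e-23, lost at adjusted p = 0.0621 with an estimated correlation). Pdlim5 (2.90 ± 0.05) was higher. 22 of 22 smooth muscle contractile genes were higher and 0 were lower (median 4.76, adjusted p = 1.55e-16, lost at adjusted p = 0.0621 with an estimated correlation). Tpm2 (3.35 ± 0.06) and Nexn (4.34 ± 0.09) were higher. 25 of 45 integrin and focal adhesion genes were higher and 10 were lower (median 0.53, adjusted p = 5.43e-04, lost at adjusted p = 0.277 with an estimated correlation). Itga5 (3.08 ± 0.05) and Tln2 (2.89 ± 0.05) were higher. Others passed in the preset test alone, the smallest value being adjusted p = 0.277 with an estimated correlation. Sarcomere and immediate early lists were higher, calcium-binding and cell cycle lists lower. Sarcomere and striated muscle genes had 22 higher and 2 lower of 31 (median 3.75, adjusted p = 0.00494). SRF-TCF immediate early genes had 18 higher and 3 lower of 25 (median 1.86, adjusted p = 1.30e-04). Calcium-binding and calmodulin genes had 14 higher and 31 lower of 56 (median -0.40, adjusted p = 0.00602). S-phase genes had 6 higher and 28 lower of 42 (median -0.27, adjusted p = 0.00602). G2/M genes had 7 higher and 33 lower of 51 (median -0.42, adjusted p = 0.00564). Ier2 (1.87 ± 0.05) was higher, and Camk1 (-1.57 ± 0.04) and Mcm5 (-0.98 ± 0.05) were lower. Calcium and potassium channel lists did not pass. Calcium pumps, channels and stores had 43 higher and 18 lower of 83 (median 1.0, adjusted p = 0.155). Potassium channels had 29 higher and 4 lower of 52 (median 1.87, adjusted p = 0.0536, passing at 0.0160 with library totals, 0.0260 without the 4 libraries of highest carry-over, 0.0453 without Y238A replicate 1, 0.0315 without wild-type replicate 3 and 0.0459 without Y238A replicate 3). Itpr3 (-1.57 ± 0.05) and Kcnn4 (-1.32 ± 0.07) were lower with wild type, and Itpr1 (1.28 ± 0.06) and Kcnh2 (2.74 ± 0.13) were higher. The edgeR test passed 6206 higher and 5599 lower genes, 3745 and 1845 by at least 2-fold, with groups non-overlapping in 72.9% of genes against 10% by chance. With library totals the median of all genes moved by -0.160 and the majority turned, to 5174 higher and 7075 lower.

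Wild-type against Y238A MRTFA in E0771 also placed muscle genes higher and interferon genes lower. Acta2 was higher by 4.86 ± 0.14. Y238A replicate 1 held AT-3-specific transcripts at 0.269% of their AT-3 Y238A level, and which group they came from was not tested. Several of the largest differences grew without that library: Actc1 was higher by 9.56 ± 0.84, or 11.16 without Y238A replicate 1, Kcnmb1 by 9.36 ± 0.43, or 10.91 without Y238A replicate 1 and Optc by 8.04 ± 0.45, or 9.21 without Y238A replicate 1. Tub (8.02 ± 0.56, or 8.78 without Y238A replicate 3) was also higher. Lower with wild type were the transporter Slco2b1 (-4.47 ± 0.64, or -5.50 without wild-type replicate 1), Apod (-4.22 ± 0.29), Iigp1 (-3.63 ± 0.43), Oas2 (-3.22 ± 0.36) and Zbp1 (-3.10 ± 0.44).

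The calls of SRF, muscle, integrin and interferon lists held with an estimated correlation in E0771. 38 of 40 MRTF-SRF cytoskeletal targets were higher and 0 were lower (38 and 1 adjusted over the list alone, median 1.64, adjusted p = 1.17e-125, held at adjusted p = 7.46e-05 with an estimated correlation). Csrp1 (2.89 ± 0.06) and Pdlim5 (2.02 ± 0.05) were higher. 18 of 22 smooth muscle contractile genes were higher and 0 were lower (19 and 0 adjusted over the list alone, median 2.35, adjusted p = 5.21e-38, held at adjusted p = 0.00257 with an estimated correlation). Tpm2 (2.32 ± 0.06) and Tpm1 (1.71 ± 0.06) were higher. 15 of 31 sarcomere and striated muscle genes were higher and 0 were lower (16 and 0 adjusted over the list alone, median 1.22, adjusted p = 7.23e-10, held at adjusted p = 0.00876 with an estimated correlation). Actn2 (4.29 ± 0.27) and Myom1 (3.37 ± 0.24) were higher. 21 of 45 integrin and focal adhesion genes were higher and 7 were lower (22 and 7 adjusted over the list alone, median 0.32, adjusted p = 3.52e-13, held at adjusted p = 0.00876 with an estimated correlation). Itga5 (2.19 ± 0.05) and Vcl (1.79 ± 0.04) were higher. 1 of 37 interferon-stimulated genes were higher and 35 were lower (median -1.66, adjusted p = 5.26e-48, held at adjusted p = 0.00645 with an estimated correlation). Irgm1 (-1.69 ± 0.07) and Oas3 (-2.75 ± 0.14) were lower. The leukocyte marker Cd68 was lower with them (-2.22 ± 0.15). Other lists reported here passed in the preset test alone, the smallest value being adjusted p = 0.209 with an estimated correlation. These were higher with wild type, apart from ribosomal proteins and S-phase genes. YAP-TEAD targets had 12 higher and 2 lower of 22 (median 0.37, adjusted p = 3.85e-06). SRF-TCF immediate early genes had 13 higher and 3 lower of 25 (median 0.38, adjusted p = 0.00223). Mesenchymal and EMT genes had 12 higher and 6 lower of 31 (13 and 7 adjusted over the list alone, median 0.35, adjusted p = 0.00223). The EMT median became -0.13 without wild-type replicate 2. Potassium channels had 10 higher and 1 lower of 52 (median 0.36 or 0.24 with bounds, adjusted p = 0.00949, lost at 0.0584 without wild-type replicate 1). The p53 targets had 7 higher and 3 lower of 26 (7 and 4 adjusted over the list alone, median 0.06, adjusted p = 0.0401, lost at 0.0507 with library totals, 0.193 without the 4 libraries of highest carry-over, 0.122 without Y238A replicate 1 and 0.0619 without wild-type replicate 3). MHC class I, antigen processing and NK ligands had 9 higher and 6 lower of 25 (10 and 8 adjusted over the list alone, median 0.08, adjusted p = 0.0446, lost at 0.0673 with library totals, 0.115 without the 4 libraries of highest carry-over, 0.0668 without Y238A replicate 1, 0.0604 without Y238A replicate 2 and 0.0741 without wild-type replicate 3). Cytosolic ribosomal proteins had 0 higher and 47 lower of 77 (1 and 60 adjusted over the list alone, median -0.16, adjusted p = 1.21e-05). S-phase genes had 4 higher and 16 lower of 42 (4 and 20 adjusted over the list alone, median -0.13, adjusted p = 0.0362, lost at 0.109 without the 4 libraries of highest carry-over, 0.0852 without wild-type replicate 1, 0.115 without Y238A replicate 1 and 0.0918 without Y238A replicate 3). Crim1 (1.14 ± 0.06) and Zfp36 (1.30 ± 0.10) were higher. Kcnip3 (4.12 ± 0.30, or 4.79 without Y238A replicate 1) and Fas (3.06 ± 0.16) were higher.

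Calcium lists did not pass between the proteins in E0771. Calcium pumps, channels and stores had 23 higher and 12 lower of 83 (24 and 12 adjusted over the list alone, median 0.15 or 0.11 with bounds, adjusted p = 0.357). Calcium-binding and calmodulin genes had 17 higher and 16 lower of 56 (17 and 17 adjusted over the list alone, median -0.02, mean 0.14, test direction up, adjusted p = 0.298). Itpr3 was lower (-0.63 ± 0.05) and Jph2 (3.49 ± 0.32) and Trpv2 (3.05 ± 0.21) were higher. The edgeR test passed 2268 higher and 2326 lower genes, 927 and 354 by at least 2-fold, with groups non-overlapping in 36.2% of genes against 10% by chance. The near balance depended on the analysis, from 1972 higher and 3247 lower with library totals to 2308 and 1844 with the line fitted alone, and the majority turned without wild-type replicates 1 or 3 or Y238A replicate 1 (2017 and 1823, 2035 and 1813, 2094 and 1876).

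Differences between wild-type and Y238A MRTFA that both lines shared included interferon genes, lower, and actins and a myosin, higher. Higher in both were Pilra (7.71 ± 0.46, or 9.24 without Y238A replicate 1 in AT-3), Actc1, Acta1 and the myosin Myh13 (7.96 ± 0.49 in E0771). Lower in both were Iigp1 (-3.62 ± 0.37) and Zbp1 (-4.18 ± 0.49, or -5.30 without wild-type replicate 3) in AT-3, with Ifit3b, Enpp2, Ifit3, Uba7, Oasl2, Irf7, Rsad2 and Ifi44. The counts were 1793 higher and 1662 lower, against 789 and 730 expected, with odds ratios of 9.54 and 7.36 in Fisher's exact test, and 468 genes passed with opposite signs. With library totals the majority turned, to 1502 higher and 2542 lower.

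Interaction tests asked where the effects of a construct differed between the lines, with positive values for a higher effect in E0771. The construct stood at 5434 CPM in AT-3 and 761 CPM in E0771 as wild type, and at 2105 and 319.7 CPM as Y238A. Differences between the lines therefore cannot be told apart from those in the amount of construct. For wild-type MRTFA against empty vector, Srf differed by -0.44 ± 0.10 (adjusted p = 0.00150, lost at 0.0629 without AT-3 wild-type replicate 3) and Mrtfa by 0.47 ± 0.06. Nebl, a thin filament protein, rose in E0771 from 0 to 0.292 CPM and stood at 1.81 and 2.18 CPM in AT-3 (log2 difference at least 4.61, from 0 counts). It was at least 4.25 for the G protein Gnaz and at most -12.53 for Heph, each with 0 counts in 1 group. E0771 kept Heph at 0.532 and 0.725 CPM. The edgeR interaction passed 4149 genes with higher and 4285 with lower effects in E0771 (5266 and 3537 with library totals), 1113 and 2154 of them by at least 2-fold. Lists past the threshold with higher effects in E0771, given by median, were MRTF-SRF cytoskeletal targets (0.28, adjusted p = 0.0316), YAP-TEAD targets (0.46, adjusted p = 0.0109), calcium-binding and calmodulin signalling genes (0.30, adjusted p = 0.0324), mesenchymal and EMT genes (0.57, adjusted p = 3.78e-04), interferon-stimulated genes (1.16, adjusted p = 2.60e-09), NF-kB and inflammatory cytokine genes (0.55, adjusted p = 0.0325), S-phase genes (0.39, adjusted p = 6.54e-05), G2/M genes (0.32, adjusted p = 1.47e-05), cholesterol synthesis genes (0.68, adjusted p = 0.0264) and cytosolic ribosomal proteins (0.54, adjusted p = 2.59e-14). Those with lower effects were SRF-TCF immediate early genes (-0.94, adjusted p = 5.85e-06), smooth muscle contractile genes (-1.09, adjusted p = 0.0324), unfolded protein and integrated stress response genes (-0.21, adjusted p = 0.0324), glycolysis and hypoxia genes (-0.27, adjusted p = 0.0338) and mitochondrially encoded genes (-0.71, adjusted p = 0.0325). All 15 of these calls were lost with an estimated correlation, the smallest value being adjusted p = 0.525 with an estimated correlation. The potassium channel and calcium pump lists, which passed in one line or neither, had differences at adjusted p = 0.253 and 0.0945.

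For Y238A against empty vector, Srf differed by 0.74 ± 0.10 and the transcription factor Tbx3 by at least 3.68, from 0 counts with Y238A in AT-3, and 2174 genes had higher and 2429 lower effects in E0771 (2715 and 2257 with the stricter filter). Lists with higher effects in E0771 were MRTF-SRF cytoskeletal targets (0.31, adjusted p = 3.99e-06), smooth muscle contractile genes (0.30, adjusted p = 0.00505), epithelial genes (0.84, adjusted p = 0.0350), S-phase genes (0.22, adjusted p = 0.00445) and cytosolic ribosomal proteins (0.52, adjusted p = 1.02e-38), and with lower effects calcium-binding and calmodulin signalling genes (-0.16, adjusted p = 0.00252) and genes of MHC class I, antigen processing and NK ligands (-0.60, adjusted p = 1.55e-07). The MHC class I call held (adjusted p = 0.0156 with an estimated correlation), and the smallest of the rest was lost at adjusted p = 0.158 with an estimated correlation. The interferon list, past the threshold in both lines, had an adjusted p = 0.872 for the difference, with a median of -0.13, a mean of -0.22 and a test direction up. For wild type against Y238A, Srf differed by -1.18 ± 0.10, Mrtfa by 0.54 ± 0.06 and Nrk by at least 5.35, from 0 counts with Y238A in E0771, and 4089 genes had higher and 4058 lower effects in E0771 (5225 and 3390 with library totals). Lists with higher effects in E0771 were calcium-binding and calmodulin signalling genes (0.54, adjusted p = 6.76e-05), mesenchymal and EMT genes (0.91, adjusted p = 0.00325), interferon-stimulated genes (1.32, adjusted p = 4.35e-09), NF-kB and inflammatory cytokine genes (0.51, adjusted p = 0.0367) and G2/M genes (0.24, adjusted p = 0.00276). Those with lower effects were SRF-TCF immediate early genes (-0.41, adjusted p = 0.00164), smooth muscle contractile genes (-1.5, adjusted p = 1.70e-04) and unfolded protein and integrated stress response genes (-0.46, adjusted p = 0.00525), and all 8 calls were lost, the smallest value being adjusted p = 0.352 with an estimated correlation.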

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

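The tests of the interferon and SRF target patterns below were chosen only after those results were seen. The carry-over tests were stated after that pattern was seen but before their own results, and the random regroupings before theirs. Whether the regroupings can judge chance was decided after their counts were seen.

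The first pattern is AT-3-specific transcripts in E0771 empty vector replicate 2. If RNA or library material of AT-3 empty vector had been carried in, each gene should show the same percent of its AT-3 level, and the median was 1.40% over 24 genes held out for the test (quartiles 1.24% and 1.55%), all 24 above both other libraries. Expression by the E0771 cells themselves is excluded, since the excess followed the AT-3 level across genes (rank correlation 0.950). AT-3 cultures with a construct are no likely source, because they would have brought 6962 or 2696 MRTFA counts and the library held 10. In AT-3 Y238A replicate 1, 131 wild-type-induced genes showed a median excess of 1.26% of the wild-type level (quartiles 0.760% and 2.40%), 105 of them above both other libraries, which is consistent with carried-over wild-type material.

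The second pattern is interferon-stimulated genes higher with Y238A MRTFA, a call that held in E0771 and was lost in AT-3 at adjusted p = 0.0629 with an estimated correlation. Scaling is excluded, as the smaller of the lines' list medians was 2.07 with library totals. Leukocytes or their RNA are excluded as the sole source, since they would bring all their markers and the upper quartiles of the 7 tested were 0.81 in AT-3 and 0.20 in E0771 (medians -0.14 and -0.31), although Cd68, Cd14 in AT-3 and, outside the list, Cd74 rose. The amount of construct transcript is excluded as the sole reason, because wild type was more abundant yet the list was lower with it than with Y238A, by medians of -3.02 in AT-3 and -1.66 in E0771. Whether Y238A protein, its construct or the making of those cultures raised these genes cannot be told from these libraries.

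The third pattern is SRF targets lower with Y238A MRTFA in AT-3, a call lost at adjusted p = 0.597 with an estimated correlation. Scaling is excluded, with list medians of -0.43 with library totals and -0.46 with DESeq2 size factors. For the amount of transcript the test reused the pattern itself, the median of -0.44 with Y238A, so its outcome was fixed and excludes nothing. A weaker form of the wild-type effect would have raised the targets, which wild type did. An effect of the amount of Y238A itself was not tested. Carried-over wild-type RNA in replicate 1 is excluded, since targets were higher with wild type (median 1.38), so that it would raise them.

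The remaining flagged results were line differences in the interaction test. Calls for Gas1 and Spata6 rest on a library with AT-3 transcripts. The others cannot be told apart from the higher amount of construct in AT-3. Fitted log2 values with at most 3 counts in a group are not exact, and bounds follow in brackets. For wild-type MRTFA against empty vector these were 8434 genes and 15 lists, with Mrtfa at 0.47, Srf at -0.44, Nebl at 7.54 (at least 4.61), Gnaz at 7.20 (at least 4.25), Heph at -15.68 (at most -12.53) and Slc35d3 at -13.01 (at most -11.47, 0.00702 and 33.7 CPM in AT-3, 0.0455 and 0.0215 CPM in E0771, call lost at adjusted p = 0.0964 without E0771 empty vector replicate 3). For Y238A against empty vector they were 4603 genes and 7 lists, with Srf at 0.74, Tbx3 at 6.65 (at least 3.68), Ntn5 at 5.56 (at least 2.56, 4.89 without AT-3 empty vector replicate 3, call lost), Gas1 at -7.39 (at most -4.36, -1.56 without E0771 empty vector replicate 2, call lost) and Spata6 at -7.00 (at most -3.97, -4.62 without the same library, call lost). For wild type against Y238A they were 8147 genes and 8 lists, with Mrtfa at 0.54, Srf at -1.18, Nrk at 8.38 (at least 5.35), Nebl at 7.13 (at least 5.52, 9.80 without E0771 Y238A replicate 2), Gpc3 at -10.90 (at most -7.92, -9.35 without the same library) and Mageb1 at -10.89 (at most -7.91).

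Libraries were also regrouped at random, and the number of groupings that gave as many genes as the real one, itself counted, is given with the highest other grouping. Within a line only 10 splits exist, too few to exclude chance: the real split was 1 of 10 in each case, with 12240 genes against at most 3, 7788 against 2 and 11805 against 1 in AT-3, and 4364 against 14, 2149 against 12 and 4594 against 2 in E0771. Over 100 regroupings, the genes shared by the lines stood at 1 of 100 for wild type against empty vector (3410 against 6) and against Y238A (3455 against 2). This cannot judge chance sharing, because a line with mixed groups had at most 14 genes called and so almost none to share. Unrelated effects would already share 728 higher and 761 lower genes for wild type against empty vector. Chance cannot be judged this way for the line differences, because groupings with the true AT-3 libraries gave 8169 to 9532 genes for wild type against empty vector (real 8434, 8 of 100), 4310 to 5627 for Y238A against empty vector (real 4603, 6 of 100) and 7671 to 8853 for wild type against Y238A (real 8147, 4 of 100) however E0771 was split, and no other grouping exceeded 181. Nor can it for the within-line overlaps (2 of 100 in each line, 4410 against 8960 in AT-3 and 725 against 2511 in E0771), because the higher grouping took the wild-type libraries as the control and mixed the rest, so the count follows the effect of that control.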

How the results depend on the processing

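Of the alternatives, the analysis without the 4 libraries of highest carry-over and the limit to genes of at least 1 CPM were chosen only after the result was seen. Of 241 recomputed counts for 13 results, 221 stayed within 1.5 times and 20 moved. Of 9683 gene values, 9385 kept direction and call, 237 lost the call (156 on leaving out 1 library), 53 gained it and 8 changed sign. Of 2016 list tests, 1755 kept both, 93 lost the call (20 on leaving out 1 library), 99 gained it and 69 changed direction, none of which passed either way. List directions were first labelled by the sign of the median, which gave 125 changes, and then by the direction of the test, which gave these 69; of 1680 recomputed medians 108 had the opposite sign, 10 in lists past the main threshold. Calls of named genes lost and gained were 5 and 12 in DESeq2, 2 and 2 with size factors, 9 and 6 with library totals and 59 and 3 without the 4 libraries. Of list calls, the estimated correlation ended 55, and fry ended 4 and added 50. A replicate block ended 6 gene calls and 8 list calls and added 6 and 11. It took p53 targets to adjusted p = 0.320 and integrins to 0.0949 in AT-3 with wild type, calcium-binding genes to 0.0585 in AT-3 with Y238A, p53 targets to 0.0780 in E0771 with wild type, and in E0771 wild type against Y238A potassium channels to 0.0741, EMT genes to 0.0769, MHC class I to 0.106 and p53 targets to 0.160. Lists that passed with the block were calcium pumps (0.0215), potassium channels (0.0360) and mitochondrial genes (0.0130) in AT-3 with wild type, cholesterol synthesis in AT-3 with Y238A (0.00867) and E0771 with wild type (0.00555), and mitochondrial genes (0.0331) and ribosomal proteins (0.0415) in E0771 with Y238A. For wild type against Y238A they were potassium channels (0.0137), cholesterol synthesis (0.00766) and ribosomal proteins (0.00170) in AT-3 and glycolysis genes in E0771 (0.0439). Of 18 same-number pairs 9 correlated above 0.1 (range -0.50 to 0.79), and 15 of 18 libraries correlated best with their own number in another construct, a hint from the data. Only for E0771 wild type against empty vector were all 3 pairs above 0.1 (0.59, 0.79 and 0.70), and its blocked list values are also given beside the results. Lists were the least stable result, and the cause was not tested.

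An added limit of 2-fold moved every count: AT-3 5850, 1844 and 5590, E0771 1085, 358 and 1281 (wild type against empty vector, Y238A against empty vector, wild type against Y238A), line differences 3267, 1011 and 3300, shared genes 865 and 929, overlaps 849 in AT-3 and 83 in E0771. Without the 4 libraries the counts that moved were 2785 and 847 in E0771 for each construct against empty vector, 2246 shared genes and an E0771 overlap of 226. Leaving out each library gave 11511–12070, 6829–7043 and 11042–11536 in AT-3, 3241–3874, 1224–2284 and 3840–4615 in E0771, 7891–8662, 4016–4849 and 7628–8332 for line differences, 2618–3688 and 2925–3568 for shared genes, and 3814–4493 and 383–776 for overlaps, the moved values being 1224 and 383 without E0771 empty vector replicate 2 and 461 without E0771 empty vector replicate 3.

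Genes that changed sign had leave-out ranges of -0.075 to 0.0011 (Mrtfa, E0771 wild type against empty vector), -0.0038 to 0.073 (Mrtfa, E0771 Y238A against empty vector), -0.22 to 0.12 (MRTFA, difference of wild type against Y238A, 0.0034 with library totals), -0.14 to 1.37 (Tek, AT-3 Y238A against empty vector), -3.17 to 0.46 (Pdpn, E0771 Y238A against empty vector) and -0.64 to 0.18 (Kdr, the same comparison, 0.37 without the 4 libraries). List tests that changed direction follow with their adjusted p, "4 out" meaning without the 4 libraries and ranges spanning every library left out. In AT-3 wild type against empty vector they were fibroblast markers 0.789 block, 0.778–0.978 leave-out. In AT-3 Y238A against empty vector they were collagens 0.290 block, 0.0558 4 out, 0.688–0.99999 leave-out, then potassium channels 0.648 fry, 0.985 size factors, 0.834–0.983 leave-out, then NF-kB genes 0.902 block, then stress response 0.993 fry, 0.566–0.99999 leave-out, then endothelial markers 0.834–0.99999 leave-out. In AT-3 wild type against Y238A they were collagens 0.539 block, 0.904 4 out, 0.532–0.935 leave-out. In E0771 wild type against empty vector they were calcium-binding genes 0.897 block, then sodium-potassium pump 0.897 block, 0.846–0.975 leave-out, then stress response 0.989 totals, 0.879 4 out, 0.811–0.971 leave-out, then mitochondrial genes 0.940 block, 0.575–0.957 leave-out. In E0771 Y238A against empty vector they were smooth muscle genes 0.339–0.999 leave-out, then integrins 0.529–0.999 leave-out, then calcium pumps 0.930 block, 0.833–0.992 leave-out, then calcium-binding genes 0.244–0.874 leave-out, then sodium-potassium pump 0.965 4 out, 0.666–0.992 leave-out, then EMT genes 0.989 size factors, 0.969 totals, 0.920 block, 0.539 4 out, 0.379–0.987 leave-out, then p53 targets 0.991 block, 0.474–0.997 leave-out, then ribosomal proteins 0.0129–0.857 leave-out, then endothelial markers 0.983 fry, 0.990 size factors, 0.870 totals, 0.746 4 out, 0.591–0.940 leave-out. In E0771 wild type against Y238A they were collagens 0.507 4 out, then sodium-potassium pump 0.661 block, 0.701–0.945 leave-out, then epithelial genes 0.882 4 out, then G2/M genes 0.0940–0.887 leave-out, then cholesterol synthesis 0.871 block, 0.999 4 out, 0.382–0.980 leave-out, then stress response 0.262–0.938 leave-out.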

Other observations

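The tests of interferon genes and SRF targets cited here were chosen only after those results were seen. A hypothesis is that Y238A MRTFA, or the DNA or RNA used to introduce it, triggers interferon signalling independent of SRF, since scaling does not account for the rise (smaller list median 2.07 with library totals). A second construct deficient in SRF binding, an uninduced Y238A culture and blocking of the interferon receptor would tell whether the protein could be the source.

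A second hypothesis is that Y238A competes with endogenous MRTF proteins in AT-3 and so may lower SRF targets (median -0.43 with library totals) while the same list did not pass in E0771, although the AT-3 call was lost at adjusted p = 0.597 and that of the line difference at 0.499 with an estimated correlation. Occupancy of SRF at Vcl and Myl9 with and without Y238A, with the transcript brought to the same level in both lines, would test it.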
